A study of Oncorhynchus mykiss with 183 samples.

How the data were processed

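Liver, ovary and pituitary RNA of female rainbow trout (Oncorhynchus mykiss) was measured on 183 spotted cDNA arrays with 2 colours each. The fish were sampled on set days after spawning and were kept either under the normal photoperiod, followed to day 330, or under a compressed photoperiod, followed to day 216. Per the labels, RNA was extracted with Trizol and labelled by the indirect cDNA method. Channel 1 carried a pooled day-0 standard in Alexa Fluor 555, and channel 2 carried the sampled fish in Alexa Fluor 647. No array has the dyes exchanged, so a dye bias of a probe stays in every comparison with the pool and cancels between days. The design text calls the replicates of a day biological replicates, 1 to an array, without saying more about the animals. Limma p-values therefore measure only the spread between arrays of a day, which may be partly technical, and not that between days.

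Each array's scanner output holds a foreground and a background intensity per spot and channel, per the file headers, together with the percent of a spot's pixels above background plus 2 SD and the percent of saturated pixels, also per the file headers. The scanner intensities are linear and were not normalized. The authors' deposited value table holds log2 ratios of channel 2 over channel 1 for 181 of the arrays. Its log2 scale and direction were found by setting each column against the scanner ratios of its array (lowest r 0.966, median r 0.9977). Its column medians lay between -0.162 and 0.295 with a middle value of -0.007. The sources used here give neither the authors' steps for background, normalization and centring nor the date or batch of printing, hybridisation or scanning.

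Every array holds 17328 spots, of which 1261 are controls. The 16067 cDNA spots make up 16028 probes, since 37 probes were spotted more than once. Of these probes, 11343 have a usable gene name in the files (5731 different ones), 4323 are listed as unknown, and 362 name several genes or a repeat. Names are those of the array's design and can be old. The reference gene table holds none of the probes' sequence identifiers, so no genome position is given.

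Foreground and background medians were corrected with normexp (offset 50), normalized by loess within each array with controls at weight 0, and averaged over spots of a probe, in limma 3.58.1 under R 4.3.3. A spot counted as detected where at least 50 percent of its pixels passed background plus 2 SD. A probe was tested in a tissue if it was detected in either channel on at least a share of 0.5 of the arrays of either photoperiod, which left 11366 probes in liver, 12629 in ovary and 11127 in pituitary. Saturated spots were kept. The number of arrays limits the precision of every value, and a test-channel spot count per array stands for depth.

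For each tissue all arrays entered a fit with a mean for each day and photoperiod (lmFit and eBayes), with 39 residual degrees of freedom in liver, 40 in ovary and 40 in pituitary. The cycle was divided into 3 equal parts, counted to day 330 or day 216, and early days were those in the first part and late days those in the last. The contrasts were late minus early in each photoperiod, early days against the day-0 pool, the difference between photoperiods in the late minus early change, and compressed minus normal over 6 pairs of days at the same phase. Days had equal weight within a contrast. The days sampled within a part of the cycle were not at the same phases in both photoperiods, so the difference between photoperiods can also hold a difference in sampled phase. P-values were adjusted by Benjamini and Hochberg over the probes tested in the tissue, at a threshold of 0.05. The comparison with the pool leaves out the pool's own spread, because it is a single control sample. A further test asked which normal day each compressed day resembled most, by Pearson correlation of day means over probes that changed across normal days, and compared elapsed days with cycle phase by a two-sided exact sign-flip permutation test.

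The groups, contrasts, gene lists, naming rule and most alternatives were fixed before the data were examined. The text names, for each late against early comparison, up to 8 genes with the largest rise and 8 with the largest fall among called genes whose late days all lay on the same side of the early mean. It adds up to 3 called members of each gene list and a set of reproductive key genes whether called or not. For the other comparisons the 5 largest rises and falls and the called list members were taken. The brightest probe stood for a gene with several, and disagreement between called probes is stated. The patterns for key genes were narrowed after the first values were printed, to drop a vitellogenin receptor and a transmembrane protein named after growth hormone. Probes named outside this rule were chosen after their values were seen, as the text says in each place. A gene not detected on any array of a group is given as a bound, from the bright group's channel mean after loess and Aquantile against the lowest detected signal of the dim arrays. Such bounds are open to dye bias.

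A gene is a distinct name in the files, so a gene under several names counts more than once in a list. The 26 gene lists were matched on gene names, and after the names, but not the values, had been seen, some wrong matches were dropped. Lists with at least 3 measured genes in a tissue were tested with camera at a preset correlation of 0.01 on the brightest probe per gene, adjusted over the lists of a comparison, and again with an estimated correlation. This gave 300 tests, of which 10 were called, and 5 stayed under the threshold with an estimated correlation.

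The procedure was tested on simulated data with 200 changed probes. The simulated noise was independent for each probe and array, so probes were uncorrelated and no array was weaker than another. Recovery and false calls in the data can therefore be worse than the rates given here. In the liver normal late against early comparison it recovered 56 percent of 100 probes changed 2-fold and 94 percent of 100 changed 4-fold, with 11 false calls. In the ovary difference between photoperiods it recovered 1 percent at 2-fold and 47 percent at 4-fold, so differences under 4-fold were mostly out of reach there. The pituitary late against early comparison recovered 74 percent and 100 percent under the normal photoperiod. A simulated list of 20 genes shifted by 0.5 was called in all 3 tissues. The alignment test found simulated cycle phase in all 3 tissues and simulated elapsed days in liver and ovary, but not in pituitary, where the permutation test gave p = 0.236. Those simulations ran on 196 to 215 probes, the real test on 40 in ovary and 3 in pituitary. They therefore do not show what the real test could find there.

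The alternatives were no background subtraction, median centring, scaling between arrays, no filter on dim probes, the authors' value table, the replicate number as a block, the day as a random block (statmod 1.5.0), array quality weights, narrower phases from a division of the cycle into 4 equal parts, and leaving out day 8, each replicate number or the arrays with disagreeing labels. Leaving out weak arrays, arrays that correlate above 0.5 with an array of another tissue, arrays whose channel 2 background exceeded 3 times the median of the tissue, arrays whose median signal was under 2-fold over background, each array and each day was added after the data were seen. Titles were followed where labels disagree. On 1 liver array of each photoperiod the characteristics give another day. On 16 arrays, 12 of them normal ovary, the description gives another replicate number. The tag that holds the day names the normal photoperiod on all 99 compressed arrays, where the treatment protocol also says compressed. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.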

Results

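Gene expression was followed through the reproductive cycle of female rainbow trout in the liver, which makes yolk and egg envelope proteins, in the ovary, and in the pituitary, which secretes the gonadotropins. The design compared fish under the normal photoperiod with fish under a compressed one, each against a pool of fish at spawning (day 0). Values are log2 ratios of a sampled fish over that pool, so 1 unit is a 2-fold difference. The liver was measured on 25 arrays under the normal photoperiod (9 days, from day 57 to day 330) and on 35 under the compressed one (12 days, from day 37 to day 216). The ovary had 30 and 31 arrays (10 and 11 days) and the pituitary 29 and 33 (10 and 12 days), in most cases 3 per day. In the sampled channel the median number of detected spots per array was 9662 and 9446 in liver, 10313 and 8250 in ovary, and 8589 and 9897 in pituitary, normal before compressed. The range was widest in the compressed pituitary, from 40 to 12597. The median signal was under 2-fold over background on 28 arrays, of which 12 were compressed ovary, 6 normal ovary, 4 normal and 2 compressed pituitary, and 1 normal and 3 compressed liver. On 7 arrays, 6 of ovary and 1 of liver, the background was over 3 times the median of the tissue.

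Arrays of a day resembled each other more than arrays of other days, with a median r of 0.13 against 0.05 in liver, 0.12 against 0.03 in ovary and 0.08 against 0.04 in pituitary. Some pairs ran against each other: r lay below -0.3 for 21 of 1770 liver pairs, 3 of 1830 ovary pairs and 5 of 1891 pituitary pairs, with lowest values of -0.48, -0.36 and -0.47. Between tissues the median r was 0.02, but 9 of 11162 pairs lay above 0.5, the highest at 0.647 between liver day 330 replicate 2 and ovary day 57 replicate 3. The 8 arrays of these pairs, all under the normal photoperiod, were 2 of liver, 3 of ovary and 3 of pituitary. On 6 of them the sampled channel resembled the mean of its own tissue most, and on that liver array (0.876 with pituitary, 0.875 with liver) and ovary day 220 replicate 2 (0.859 with liver, 0.834 with ovary) it did not. The direction of the ratios was kept because the labels state the dye of each channel and fish at different phases can oppose each other. The pool channel correlated between photoperiods at 0.879 in liver, 0.872 in ovary and 0.897 in pituitary (Spearman), against 0.885, 0.921 and 0.915 within the normal photoperiod and 0.912, 0.858 and 0.874 within the compressed one.

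**Figure D1:**
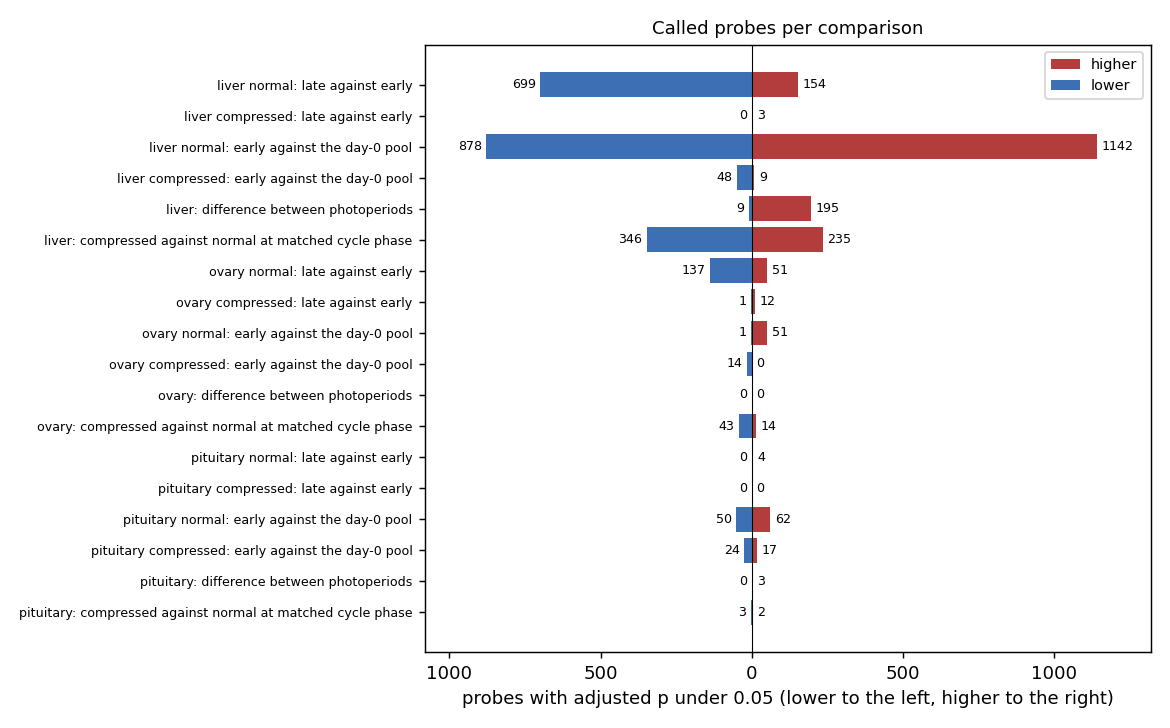
Number of probes called higher or lower by limma (adjusted p under 0.05) in each comparison and tissue, with bars for lower probes to the left and for higher probes to the right. The liver normal photoperiod holds the highest counts, with 853 probes for late against early days and 2020 for early days against the day-0 pool.

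In the liver under the normal photoperiod, vitellogenin, the yolk precursor, rose 6.09-fold from early to late days (log2 2.61 ± 0.46 SE, 12 late against 6 early arrays, limma adjusted p = 9.21e-05), and all 12 late arrays lay above the early mean. That probe was saturated on 4 of 60 arrays. The second probe, saturated on 0, rose 5.12-fold (2.36 ± 0.49, adjusted p = 0.00096). Zona pellucida sperm-binding protein 3, an egg envelope protein, rose 2.44-fold (1.29 ± 0.18, adjusted p = 2.1e-06). Several plasma proteins moved the other way. Serum amyloid P-component, a pentraxin of innate defence, fell 22.0-fold (-4.46 ± 0.52, adjusted p = 4.74e-08), and serum albumin 2, the main carrier protein of plasma, fell 12-fold (-3.59 ± 0.46). C-reactive protein, another pentraxin, was detected on 6 of 6 early and 0 of 12 late arrays, and fell (adjusted p = 3.29e-08). The size of its fall is uncertain: the sampled channel alone gave a bound of at least 7.19-fold, while the fitted ratio to the pool changed by -2.71.

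Of the 32 measured genes of the acute phase, complement and clotting list, 14 fell, 0 rose and 18 were not called, or 20 and 1 adjusted over the list alone. Their median change was -0.87 (camera adjusted p = 3.14e-13; adjusted p = 0.00257 with an estimated correlation). Complement factor B, which starts the alternative pathway, fell by 2.72 on the log2 scale. Among 20 genes of lipid transport 5 fell and 1 rose, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.659). Their median of 0.05 and mean of -0.16 differed in sign, and the test pointed down. Those that fell included apolipoprotein A-I-1, the main protein of high-density lipoprotein, at -2.64 ± 0.45, apolipoprotein CII, an activator of lipoprotein lipase, at -1.85 ± 0.33, and apolipoprotein A-I-2 at -1.48 ± 0.38. Collagen alpha-1(I), a matrix protein, fell 9.07-fold, angiogenin-2, a secreted ribonuclease, 7.25-fold, and a probe similar to rhotekin-2 6.89-fold. Each was lower on at least 11 of the 12 late arrays.

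Of 6 egg envelope and yolk genes 2 rose and 1 fell, the same counts adjusted over the list alone (camera adjusted p = 0.186), the latter a probe named for the Rivulus vitellogenin gene at -1.11 ± 0.31 and detected on 1 of 12 late arrays. Zona pellucida proteins 2 and 4 changed by 0.27 ± 0.28 and 0.20 ± 0.25 and the estrogen receptor, through which estradiol drives both groups, by 0.56 ± 0.26, none of them called. Other rises were glycerol-3-phosphate dehydrogenase 1-like protein (2.29 ± 0.54), leukocyte cysteine proteinase inhibitor 1 (1.60 ± 0.41), aldolase B, an enzyme of fructose breakdown (1.16 ± 0.34), and the histone H4-like (2.24 ± 0.71), HES6-like (2.08 ± 0.57), C1orf69 (1.94 ± 0.50), CMP-sialic acid transporter (2.06 ± 0.66) and G patch protein 8 (3.22 ± 0.94) probes. Aldolase B turned to -0.20 with the mean of its 6 probes. Hsc70, a chaperone, fell by 0.71, protein disulfide-isomerase, a folding enzyme, by 1.28, and cytochrome P450 3A45, a detoxification enzyme, by 1.41. Ribosomal protein SA fell by 1.20, S25 by 0.98 and L34 by 0.96 among 73 ribosomal proteins of which 3 fell and 0 rose, with 0 of either adjusted over the list alone (camera adjusted p = 0.993). Of lists for other cells, 2 immune genes rose and 3 fell of 60, 1 blood gene rose of 12, 1 muscle gene fell of 29 and 0 of 16 exocrine genes were called, with camera adjusted p of 0.697, 0.993, 0.659 and 0.657. Adjusted over the list alone, 2 immune genes rose and 4 fell, 1 blood gene rose, 0 muscle genes were called, and 1 exocrine gene rose and 1 fell.

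Across the array, 853 of 11366 probes were called, 154 higher and 699 lower, and 661 of them changed at least 2-fold. The median background was 600.5 on early and 337.5 on late arrays. The count was 440 to 624 without 1 of the replicate numbers, 491 without day 92, 448 with scaling between arrays (33 higher, 7.37 percent in place of 18.1) and 459 with narrower early and late phases. Without day 92 replicate 2 or 3 the higher calls numbered 507 of 1232 and 483 of 1184. Vitellogenin, zona pellucida protein 3, serum amyloid P, albumin 2, C-reactive protein and complement factor B kept their calls in all 17 alternatives that were run for them.

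**Figure D2:**
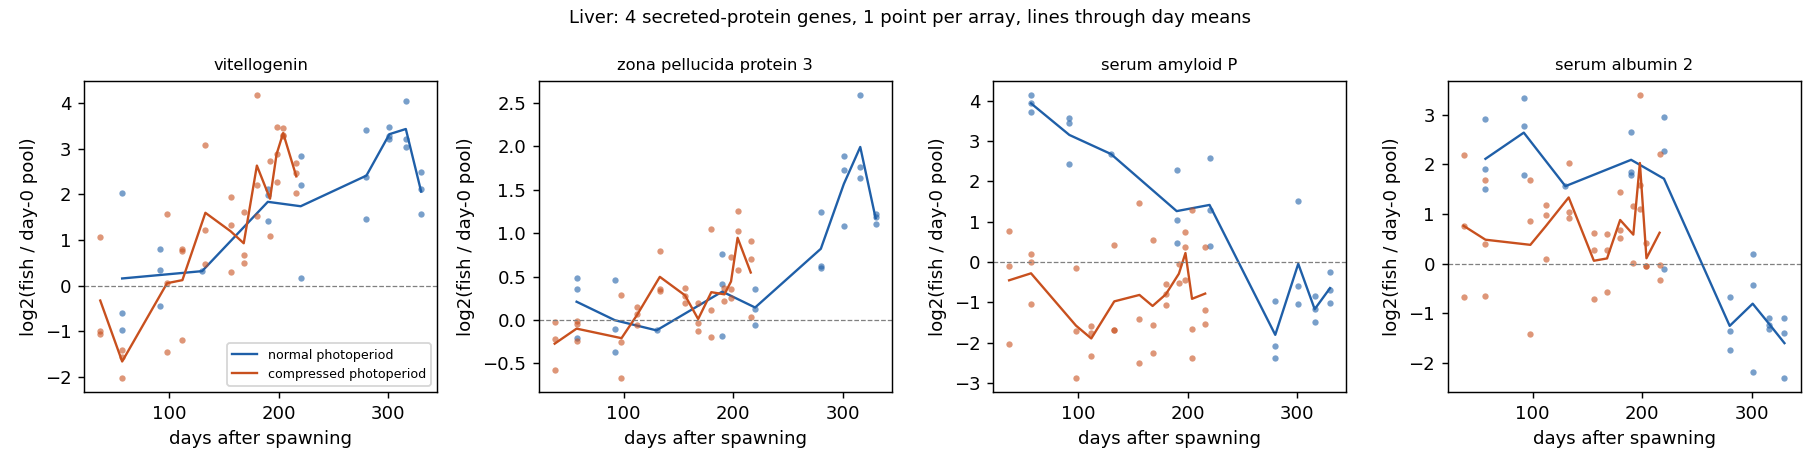
Log2 ratios to the day-0 pool in liver by day after spawning for vitellogenin, zona pellucida protein 3, serum amyloid P and serum albumin 2, with 1 point per array and lines through day means (blue normal, orange compressed photoperiod). Vitellogenin reached a day mean of 3.43 on day 316 under the normal photoperiod and 3.34 on day 204 under the compressed one.

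Under the compressed photoperiod vitellogenin rose 9.02-fold in the liver (3.17 ± 0.43, 20 late against 6 early arrays, adjusted p = 3.63e-05), on 20 of 20 late arrays, and its second, unsaturated probe rose 5.50-fold (2.46 ± 0.46, adjusted p = 0.0179). Its day mean went from -1.66 ± 0.32 (SD, n = 3) on day 57 to 3.34 ± 0.10 (SD, n = 3) on day 204. Of the 6 egg envelope and yolk genes 1 rose, or 3 adjusted over the list alone, with a median of 0.23 (camera adjusted p = 0.00234; adjusted p = 0.0286 with an estimated correlation). This list call was lost without replicate 1 (adjusted p = 0.244, with a range over its 15 alternatives from 0.000948 to 0.244). Zona pellucida protein 3 had 0.59 ± 0.17 (adjusted p = 0.526) and the estrogen receptor -0.06 ± 0.25, neither called. The acute phase list had a median of -0.10 with 0 of 32 members called (camera adjusted p = 0.123). In all 3 of 11366 probes were called, the third an unknown one detected on 0 of 6 early and 11 of 20 late arrays (at least 2.54-fold higher, adjusted p = 0.033), and limma gave 523 at an unadjusted p under 0.05. Without replicate 2 or 3 the vitellogenin call was lost, at 3.09 and 3.07, and without day 204 the count was 1. It was 5 without normal day 316 replicate 1, compressed day 37 replicate 1 or compressed day 216 replicate 1, and 1 without compressed day 37 replicate 2 or day 57 replicate 2.

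The difference between photoperiods in these liver changes was tested directly. Late days ran from 280 to 330 under the normal photoperiod and from 156 to 216 under the compressed one, which began earlier in the last part of its cycle. A difference in sampled phase can therefore add to the values. Compressed minus normal, the late against early changes of several plasma proteins were more positive. Serum amyloid P differed by 4.19 ± 0.71 (18.2-fold, adjusted p = 0.000412), serum albumin 2 by 3.59 ± 0.63 (12.1-fold, adjusted p = 0.000511), apolipoprotein A-I-1 by 3.39 ± 0.62, plasma retinol-binding protein II, the carrier of vitamin A, by 3.04 ± 0.53 and C-reactive protein by 2.06 ± 0.42. Of the 32 acute phase, complement and clotting genes 7 were higher in this difference and 0 lower, or 13 and 0 adjusted over the list alone, with a median of 0.73 (camera adjusted p = 1.22e-09; adjusted p = 0.0163 with an estimated correlation). They included complement factors H (1.88 ± 0.43) and B (1.94 ± 0.53), coagulation factor XIII B (2.20 ± 0.53), antithrombin-III, an inhibitor of clotting (1.54 ± 0.39), and fibrinogen gamma, the clot protein (1.37 ± 0.34). In the opposite direction, glycerol-3-phosphate dehydrogenase 1-like protein differed by -2.81 ± 0.74 and the vacuolar proton ATPase subunit a1 by -1.24 ± 0.35, and both lost their calls without the 1 liver array of high background and without the 4 liver arrays of low signal over background. Vitellogenin differed by 0.57 (adjusted p = 0.79), so its rise was not shown to differ between photoperiods.

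The count was 204 probes, 195 higher and 9 lower. It was 63 without compressed day 57, 126 without compressed day 37 or without compressed day 57 replicate 1, 103 with scaling between arrays, and 18 to 82 without 1 of the replicate numbers. Without normal day 92 replicate 2 or 3 the lower calls numbered 62 of 269 and 57 of 256. Without replicate 1 the calls of serum amyloid P (3.67), albumin 2 (2.04) and apolipoprotein A-I-1 (2.75) were lost. Immune, blood, muscle and exocrine genes had 0 calls in this difference, with camera adjusted p of 0.724, 0.997, 0.724 and 0.707, and adjusted over the list alone 1 exocrine gene was lower.

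**Figure D3:**
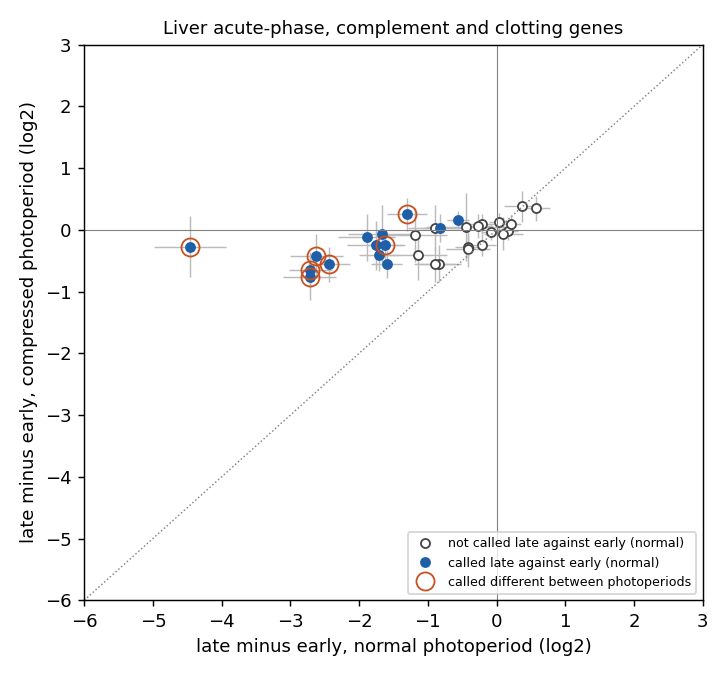
Late minus early log2 change of each acute phase, complement and clotting gene in the liver under the normal photoperiod (horizontal axis) and the compressed one (vertical axis), with SE bars, filled points for genes called under the normal photoperiod, rings for genes called different between photoperiods and a dotted line of equal change. The median was -0.87 under the normal and -0.10 under the compressed photoperiod, and the 7 ringed genes lie above the line.

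Against the day-0 pool, the early normal livers (6 arrays, days 57 and 92) had more of several plasma protein transcripts. Serum amyloid P was 11.7-fold higher (3.54 ± 0.43, adjusted p = 5.53e-08, 6 of 6 arrays), apolipoprotein A-I-1 6.47-fold, C-reactive protein 5.83-fold, and the antiviral Mx 5.83-fold (2.54 ± 0.34). Of the 32 acute phase genes 14 rose and 1 fell, or 16 and 3 adjusted over the list alone, with a median of 0.51 (camera adjusted p = 1.34e-05; adjusted p = 0.169 with an estimated correlation). Complement factor H rose by 2.06 ± 0.26, coagulation factor XIII B by 1.88 ± 0.32 and fibrinogen beta by 1.26 ± 0.33. Of 69 genes of mitochondrial respiration 12 fell and 1 rose, the same counts adjusted over the list alone (camera adjusted p = 0.211), among them ATP synthase e chain at -0.84 ± 0.20 and subunit QP-C of the cytochrome bc1 complex at -0.71 ± 0.13. Of 73 ribosomal proteins 6 rose, such as S25 at 1.59 ± 0.25 and L34 at 1.5 ± 0.24, or 5 adjusted over the list alone (camera adjusted p = 0.575). Of other cell types, 4 muscle genes fell and 2 rose of 29, 3 blood genes fell of 12, and 6 immune genes fell and 5 rose of 60, with camera adjusted p of 0.55, 0.866 and 0.55. Adjusted over the list alone the counts were the same for muscle and blood, and 7 immune genes fell and 5 rose. The largest falls, G patch protein 8 at -2.37 ± 0.76 and the CMP-sialic acid transporter at -2.26 ± 0.54, varied between arrays with SDs of 3.54 and 2.24. In all 2020 probes were called, 1142 higher and 878 lower, and 1132 without day 92. With scaling between arrays 804 of 1184 were higher, 67.9 percent in place of 56.5. A dye bias of a probe can add to these values, but it would be the same on the early compressed livers. There serum amyloid P had -0.37 ± 0.43, C-reactive protein 0.22, complement factor H 0.16 and coagulation factor XIII B -0.36, none of them called.

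The early compressed livers (6 arrays, days 37 and 57) had less of several plasma protein transcripts than the pool. Haptoglobin, the hemoglobin-binding plasma protein, was 6.63-fold lower (-2.73 ± 0.48, adjusted p = 0.0012, 6 of 6 arrays), apolipoprotein A-I-1 3.31-fold (-1.73 ± 0.37), fibrinogen beta 2.76-fold (-1.47 ± 0.33) and fibrinogen gamma 1.79-fold. Biotinidase, which recycles the vitamin biotin, was 5.26-fold higher (2.40 ± 0.34, adjusted p = 7.83e-05) and protein arginine N-methyltransferase 1 was 2.58-fold higher. Of the 32 acute phase genes 3 fell and 0 rose, or 4 and 0 adjusted over the list alone, at a median of -0.12 (camera adjusted p = 0.000163; adjusted p = 0.335 with an estimated correlation). The count was 57 probes, 9 higher and 48 lower, but 7 without day 37, 19 without day 57, 36 without day 37 replicate 3 and 22 without day 57 replicate 1. With scaling between arrays 29 of 95 were higher, 30.5 percent in place of 15.8. Immune, blood, muscle and exocrine genes had 0 calls, also adjusted over the list alone (camera adjusted p of 0.901 to 0.914).

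At the same phase of the cycle, compressed livers (18 arrays) stood below normal livers (18 arrays) in several plasma proteins. Apolipoprotein A-I-1 was 3.87-fold lower (-1.95 ± 0.30, adjusted p = 4.12e-05), fibrinogen beta 3.05-fold (-1.61 ± 0.27), haptoglobin 2.82-fold and fibrinogen gamma 2.00-fold (-1.0 ± 0.17), and biotinidase was 3.69-fold higher (1.89 ± 0.28). Zona pellucida protein 3 was 1.56-fold lower (-0.65 ± 0.12), but a second called probe of it went the other way and the mean of its probes was -0.06. Of the 32 acute phase genes 6 fell and 0 rose, or 12 and 3 adjusted over the list alone, with a median of -0.25 (camera adjusted p = 0.000513; adjusted p = 0.464 with an estimated correlation). Of 69 respiration genes 5 rose and 1 fell, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.342), and of 29 muscle genes 2 rose, or 5 adjusted over the list alone (camera adjusted p = 0.382). The count was 581: 235 higher (40.4 percent) and 346 lower. It was 1463 (60.3 percent higher) under median centring and 73 to 288 (13.7 to 29.8) without 1 replicate number. It was 107, 291 or 284 without normal day 57, 92 or 316 and 113, 256 or 280 without compressed day 37, 57 or 204. These values assume 1 pool for both photoperiods.

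In the ovary under the normal photoperiod, 2 egg envelope transcripts, ZPAX and zona pellucida protein 3, fell from early to late days. ZPAX fell 3.39-fold (-1.76 ± 0.31, 12 late against 12 early arrays, adjusted p = 0.000571), on 12 of 12 late arrays, and zona pellucida protein 3 fell 2.22-fold (-1.15 ± 0.28, adjusted p = 0.0193), also on 12 of 12. Of the 7 egg envelope and yolk genes these 2 fell and 0 rose, the same counts adjusted over the list alone, with a median of -0.35 (camera adjusted p = 0.542). Transferrin, the iron carrier of plasma, fell 5.58-fold (-2.48 ± 0.37), ferritin H-3, the iron storage subunit, 4.1-fold, and fatty acid-binding protein 1 2.89-fold. A probe similar to rhotekin-2 fell 12.3-fold (-3.63 ± 0.50), 5S ribosomal RNA 5.33-fold and KIAA1279 5.15-fold. Heterogeneous nuclear ribonucleoprotein K, which binds RNA, fell by 2.20, ribosomal protein L15 by 2.07, and zinc finger protein 585A by 2.56, the last with a second called probe going the other way. Among the rises were SCO1, which assembles cytochrome c oxidase, at 1.90 ± 0.41, a CCCH zinc finger protein with a G patch at 1.87 ± 0.35, COMM domain protein 5 at 1.61 ± 0.33, the carnitine transporter OCTN2 at 1.49 ± 0.34, a 14-3-3 protein at 1.44 ± 0.35 and isoleucyl-tRNA synthetase at 1.19 ± 0.32.

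Genes of steroid synthesis were not called in the ovary. The StAR probes, for the carrier of cholesterol into mitochondria, gave 0.74 ± 0.41 and 0.62 ± 0.30. Aromatase B, the only aromatase named on the array, gave -0.58 ± 0.42 and 3 beta-hydroxysteroid dehydrogenase -0.19 ± 0.39. Of 6 steroid synthesis genes 0 were called, also adjusted over the list alone (camera adjusted p = 0.498). Blood, muscle, nerve, exocrine, immune and liver-secreted genes had 0 calls too (camera adjusted p of 0.498 to 0.943), and adjusted over the list alone 1 blood gene rose. Those counts take the brightest probe of a gene. Over all 53 hemoglobin probes 2 rose and 0 fell, with a median of 0.03. P450 side-chain cleavage was not measured well enough to test, and P450 17, the gonadotropin receptors, GDF9 and BMP15 were not named on the array. In all 188 of 12629 probes were called, 51 higher and 137 lower, against a median change of all probes of -0.16. The calls numbered 69 without day 8, 87 without day 108, 480 without day 316, 671 without day 260 replicate 3, 480 without day 301 replicate 1, 119 without day 301 replicate 2 and 114 without day 57 replicate 1. Without the 3 arrays that resembled arrays of another tissue they numbered 114. Background differed between the phases, with a median of 368 on early and 838 on late arrays, and without the arrays of high background, of which 3 were late and 0 early, the calls numbered 78, 17 higher and 61 lower. Median centring gave 554 with 251 higher, a share of 45.3 percent in place of 27.1, and no filter on dim probes gave 400 with 228 higher. ZPAX, transferrin and KIAA1279 kept their calls in all 18 alternatives run for them, whereas zona pellucida protein 3 lost its call in 9, among them that without the arrays of high background (-1.06).

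Under the compressed photoperiod the ovary's calls were mostly hemoglobins of red blood cells, 10 of 13, named here after their values were seen. A hemoglobin beta probe rose 7.53-fold (2.91 ± 0.53, 20 late against 5 early arrays, adjusted p = 0.00457) and a hemoglobin alpha-4 probe at least 3.01-fold (adjusted p = 0.000711). The first was detected on 1 of 5 early and 13 of 20 late arrays, so the size of its rise is uncertain. The second was detected on 0 of 5 and 9 of 20, and 7 of the 10 were not well above background on any early array. Of 53 hemoglobin probes tested, 10 rose, 0 fell and 34 were above 0 (median 0.38, range -1.43 to 2.91), and 16 were saturated on at least 1 array. The 10 called were dim (mean log2 signal 9.1 to 11.08), and probes at 12.02 or above gave -1.43 to 0.39. By the brightest probe per gene, 0 of 13 blood genes were called, or 2 rose adjusted over the list alone (camera adjusted p = 0.152). Ubiquitin hydrolase L1 rose by 2.17 ± 0.43, and of 2 unknown probes 1 rose and 1 fell. Zona pellucida protein 3 had -1.12 ± 0.35 (adjusted p = 0.429), with 20 of 20 late arrays below the early mean. The 7 egg envelope and yolk genes had a median of 0.24 and a mean of -0.26, and the test pointed down (camera adjusted p = 0.646). Of them 0 were called, or 2 lower adjusted over the list alone. The 13 calls became 0 without day 51, 22 without day 168, 4 without day 37 replicate 1, 5 without day 51 replicate 3 and 20 without day 198 replicate 2, a weak array. The median background was 446 on early and 788 on late arrays, and 11 late and 0 early arrays had low signal over background. Without those arrays 16 probes were called, 12 higher and 4 lower, and the calls of 3 hemoglobin probes and ubiquitin hydrolase L1 were lost. Under median centring 37 of 52 calls were higher and with scaling between arrays 43 of 84, 71.2 and 51.2 percent in place of 92.3. All 10 hemoglobin calls and that of ubiquitin hydrolase L1 were lost without replicate 1 (hemoglobin beta 2.92, ubiquitin hydrolase 2.12).

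No probe of 12629 differed between photoperiods in the ovary's late against early change by limma (0 called, 531 at an unadjusted p under 0.05). In simulated data 1 percent of 2-fold and 47 percent of 4-fold changes were recovered there. The ovary count was 2 without compressed day 198 replicate 2 or day 37 replicate 1, and 1 without compressed day 198 replicate 3 or day 37 replicate 3, or without the arrays of high background. It was 5 with scaling between arrays and 21 with array quality weights. Of the 53 hemoglobin probes 0 were called in this difference, with a median of 0.59. Zona pellucida protein 3 and transferrin, which fell in the normal ovary, were not shown to differ between photoperiods.

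Against the day-0 pool, early normal ovaries (12 arrays) had more of a rhotekin-2-like probe (2.27 ± 0.35, 4.82-fold), Mx (1.95 ± 0.33, 3.86-fold, adjusted p = 0.000325), the lysosomal LAMP3 (1.84 ± 0.29) and 5S ribosomal RNA (1.83 ± 0.28), and less epiphycan, a matrix proteoglycan (-1.09 ± 0.26). In all 52 probes were called, 51 higher and 1 lower, and the count was 30 without day 8, 28 without day 80 and 21 without day 108. Without replicate 3 the call of Mx was lost (2.09). Early compressed ovaries (5 arrays) had less fibronectin, a matrix protein, 5.87-fold by the first probe (-2.55 ± 0.30, adjusted p = 3.96e-07, 5 of 5 arrays) and 5.38-fold by the second, less of the serine protease ami (-2.02 ± 0.44) and less of the macrophage colony-stimulating factor receptor (-1.89 ± 0.40). ATP-dependent DNA helicase 2 subunit 1 had -2.27 ± 0.45. Of 45 ovulation protease and matrix genes 2 fell and 0 rose, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.0143; adjusted p = 0.16 with an estimated correlation). The list call was also lost with median centring, with no filter on dim probes and without replicate 2 or 3 (adjusted p = 0.0665, 0.053, 0.298 and 0.0665, in a range over 14 alternatives from 0.00575 to 0.298), and without the arrays of low signal over background. Blood and muscle genes had medians of -0.09 and -0.09 there (camera adjusted p = 0.0704 and 0.0704). All 14 called probes were lower, while with scaling between arrays 44 of 157 were higher. The count was 33, all lower, without the arrays of low signal over background, where the call of the serine protease ami was lost (-2.02). It was 1 without day 37 or day 51, 22 without day 112 or day 198 and 24 without day 78. Without single arrays it was 4 (day 51 replicate 3), 6 (day 37 replicate 1), 8 (day 37 replicate 3, day 51 replicates 1 and 2) and 22 (day 78 replicate 2, day 198 replicates 2 and 3).

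At the same phase, compressed ovaries (16 arrays) had less of the macrophage colony-stimulating factor receptor (-1.33 ± 0.30, 2.51-fold) and fibronectin (-1.01 ± 0.23, 2.02-fold, adjusted p = 0.0211) than normal ovaries (18 arrays). Collagen alpha-1(XI), detected on 0 of 16 compressed and 8 of 18 normal arrays, was lower too (adjusted p = 0.0409), with no bound above 1. The largest falls were in SJCHGC03009 (-1.79 ± 0.38), VCRE3034 (-1.70 ± 0.36), a retroviral polyprotein (-1.67 ± 0.35), protein phosphatase 6 (-1.67 ± 0.40) and an rRNA promoter binding protein (-1.65 ± 0.40). The histone methyltransferase SETDB1-B rose by 1.22 ± 0.29, cytochrome c oxidase VIIa by 1.03 ± 0.26 and RhoGAP 17 by 0.96 ± 0.19. The count was 57 probes, 14 higher and 43 lower, or 24.6 percent higher. This share was not stable: 6 of 159 calls were higher under median centring (3.77 percent), 1 of 44 without the weak arrays, 103 of 184 without normal day 260 replicate 3 and 159 of 358 without compressed day 198 replicate 2. The count was 2 without compressed day 168, 6 without normal day 260, and 12 without normal day 280. Without compressed days 37, 78 and 180 it was 31, 92 and 27, and without normal day 57 it was 30. Further arrays gave 20 (compressed day 37 replicate 3), 33 (day 168 replicate 2, day 180 replicate 1), 36 (day 51 replicate 3) and 91 (day 78 replicate 1). In the normal photoperiod they gave 30 (day 57 replicate 3), 37 (day 280 replicate 2), 36 (day 316 replicate 2) and 98 (day 301 replicate 1). Without the 3 arrays that resembled arrays of another tissue the count was 25. It was 34 without the arrays of high background, where the calls of fibronectin (-0.96), SJCHGC03009, protein phosphatase 6, SETDB1-B and cytochrome c oxidase VIIa were lost.

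In the pituitary under the normal photoperiod, gonadotropin beta-2, the subunit that defines luteinizing hormone, rose from early to late days on 2 of its 5 probes, 11.9-fold (3.58 ± 0.51, 17 late against 9 early arrays, adjusted p = 3.52e-05) and 11.2-fold (3.48 ± 0.47, adjusted p = 1.73e-05). These probes were named after their values were seen, because the brightest probe, which stands for the gene, gave 0.55 ± 0.20 (adjusted p = 0.826) and was saturated on 6 of 62 arrays. The other 2 probes gave 0.76 ± 0.63 and 2.90 ± 0.74, not called. Early and late detection of the called probes was 1 of 9 and 15 of 17 for the first, and 5 of 9 and 17 of 17 for the second. Both folds are therefore set against signals often not well above background, and their size is uncertain. A probe named ATP synthase subunit g, for a part of the mitochondrial ATP synthase, rose 16.3-fold (4.03 ± 0.47, adjusted p = 7.23e-07), while the other 6 probes of that name lay between -0.12 and 0.28. An unknown probe at 1.33 ± 0.25 was the fourth and last call among 11127 probes, and 648 lay at an unadjusted p under 0.05. The luteinizing hormone calls were lost without replicate 2 (3.06 and 3.30), and the first also without replicate 3 (3.53). The count was 19 without day 280 replicate 1, 11 without day 80 replicate 1 and 7 without day 251. Without the arrays of low signal over background it was 12, 4 higher and 8 lower.

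**Figure D4:**
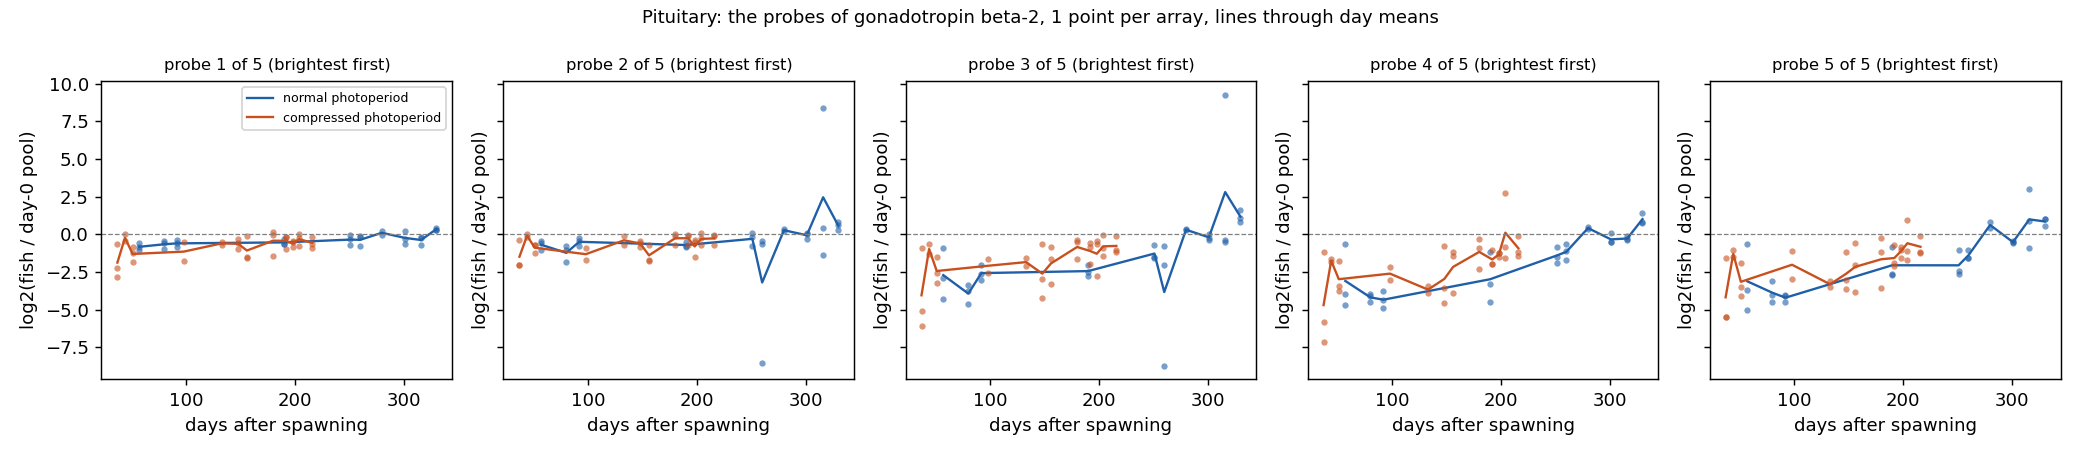
Log2 ratios to the day-0 pool in the pituitary by day after spawning for the 5 probes of gonadotropin beta-2 in order of brightness, with 1 point per array and lines through day means (blue normal, orange compressed photoperiod). The called probes, the dimmest 2, rose 11.9-fold and 11.2-fold under the normal photoperiod, from early signals often not well above background, while the brightest, saturated on 6 of 62 arrays, changed by 0.55.

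Other hormone genes did not pass the test in the normal pituitary. Follicle-stimulating hormone beta gave 0.11 ± 0.17, growth hormone -0.16 ± 0.36, prolactin -0.18 ± 0.40, thyrotropin beta -0.33 ± 0.45, somatolactin 0.39 ± 0.42 and POMC A, the precursor of corticotropin, -0.04 ± 0.38. Other names on the array gave -0.37 to -1.03 for growth hormone, 0.25 for prolactin and -0.01 and 0.16 for somatolactin, none called. Of 19 hormone names, of which several stand for the same hormone, 0 were called by the brightest probe, also adjusted over the list alone, with a median of -0.04 and a mean of -0.08 but a test pointing up (camera adjusted p = 0.98). Under the compressed photoperiod (21 late against 8 early arrays) the list had a median of 0.25 with 17 of 19 above 0 and 0 called, also adjusted over the list alone (camera adjusted p = 0.000646; adjusted p = 0.361 with an estimated correlation; 0.504 with median centring, in a range over 14 alternatives from 8.35e-06 to 0.504). The 4 names of the glycoprotein alpha subunit, shared by the gonadotropins and thyrotropin, had 0.89, 0.26, 0.14 and 0.13. The 2 of prolactin had 0.72 and 0.53, and the 5 of growth hormone had 0.68, 0.37, 0.16, 0.08 and 0.06. The luteinizing hormone probes named above gave 1.70 ± 0.52 (adjusted p = 0.496) and 1.37 ± 0.48 (adjusted p = 0.54). Limma called 0 probes, with 717 at an unadjusted p under 0.05. Leaving out compressed day 44 replicates 1 and 2 in turn gave 3 and 6 calls, day 37 replicates 1 and 2 gave 4 and 1, day 148 replicate 2 gave 1 and normal day 316 replicate 1 gave 2. Without compressed days 37, 44 and 51 there were 1, 2 and 1 calls. Without the arrays of low signal over background there were 37, 30 higher and 7 lower.

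Against the day-0 pool both early groups were low in luteinizing hormone beta. In early normal pituitaries (9 arrays) its probes were 14.6-fold (-3.87 ± 0.41, adjusted p = 1.2e-08), 13.3-fold (-3.73 ± 0.38) and 8.37-fold lower (-3.07 ± 0.59), and the brightest 1.62-fold (-0.69 ± 0.16, 9 of 9 arrays). The sampled channel was detected on 1, 5 and 6 of the 9 arrays for the first 3 probes, so the size of their folds is uncertain, and on 9 for the brightest. The brightest probe lost its call, at -0.73, without the 3 arrays that resembled arrays of another tissue. The ATP synthase subunit g probe was 17-fold lower (-4.09 ± 0.38). Rhotekin-2-like (2.63 ± 0.33), TMEM77 (1.94 ± 0.23), VCRE3034 (1.93 ± 0.33), Mx (1.89 ± 0.33) and LAMP3 (1.85 ± 0.26) were higher, as was neuroendocrine convertase 2, a prohormone protease (0.75 ± 0.18). COMM domain protein 6 (-1.16 ± 0.22), KIAA1310 (-0.93 ± 0.24) and somatostatin-2 (-0.47 ± 0.11) were lower. Of the 19 hormone names 1 fell and 0 rose, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.804). Of 10 genes of hormone processing and receptors, somatostatin-2 fell and neuroendocrine convertase 2 rose (the same counts adjusted over the list alone, camera adjusted p = 0.846). Of 68 respiration genes 1 fell, or 2 adjusted over the list alone (camera adjusted p = 0.0515). Without replicate 3 the call of Mx was lost (1.47). The count was 112 probes, 62 higher and 50 lower, or 55.4 percent higher. This share was not stable: 53 of 66 calls were higher under median centring (80.3 percent), 166 of 367 with scaling between arrays (45.2 percent), 270 of 615 with array quality weights (43.9 percent), and 105 of 402 and 91 of 325 without day 80 replicates 1 and 2. Without the arrays of low signal over background 128 of 193 were higher. The count was 247 without the weak arrays, 50 without day 80 replicate 3 and 44 without day 80. It was 57 without day 57, 185 without day 316, 179 without day 316 replicate 1, 74, 73 and 68 without day 57 replicates 1, 2 and 3, and 70 and 63 without day 92 replicates 1 and 3. Without the 3 arrays that resembled arrays of another tissue it was 41.

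In early compressed pituitaries (8 arrays) 3 of the 19 hormone names fell, of which 2 stand for the glycoprotein alpha subunit, or 10 fell and 1 rose adjusted over the list alone. The median was -0.39 (camera adjusted p = 1.36e-11; adjusted p = 0.00296 with an estimated correlation). Luteinizing hormone beta was 2.19-fold lower by its brightest probe (-1.13 ± 0.18) and 8.80-fold and 7.31-fold by dimmer ones, of which 1 was detected on 7 and the other on 6 of the 8 arrays, and 2 of the 4 glycoprotein alpha names were 3.59-fold and 2.45-fold lower (-1.84 ± 0.27 and -1.29 ± 0.26). The other 2 had -0.52 and -0.35 (adjusted p = 0.245 and 0.353). COMM domain protein 6 fell by 1.61 and a probe similar to B1160F02.4 by 1.96, while tripeptidyl-peptidase 2 (1.01 ± 0.24), properdin, a complement protein (0.78 ± 0.17), and the 52 kDa Ro protein (0.65 ± 0.16) were higher. The count was 41 probes, 17 higher and 24 lower, against 105 without the weak arrays, 157 without the arrays of low signal over background (64 higher and 93 lower), 85 without normal day 316 replicate 1, 62 without compressed day 156 replicate 2, and 18, 23 and 20 without days 37, 44 and 51. Median centring gave 68 with 4 higher, 5.88 percent in place of 41.5.

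Between photoperiods the late against early change differed for 3 pituitary probes, all more positive under the compressed one: rhotekin-2-like by 2.99 ± 0.59 (7.95-fold, adjusted p = 0.0273), TMEM77 by 2.15 ± 0.41 (4.43-fold) and an unknown probe by 1.98 ± 0.38. The luteinizing hormone probes differed by -1.88 (adjusted p = 0.861) and -2.11 (adjusted p = 0.543), so a weaker rise under the compressed photoperiod was not shown. For the hormone list the difference had a median of 0.28 (camera adjusted p = 0.0513). The 3 calls became 0 with day as a random block, without replicate 1 or 3, without the 3 arrays that resembled arrays of another tissue, and without normal day 57 replicate 3 or day 92 replicate 3. They became 0 too without compressed day 37 replicates 1 or 3, day 44 replicate 1 or day 51 replicate 1. The count rose to 84 (80 higher and 4 lower) without the arrays of low signal over background, 18 without normal day 301 replicate 2, 14 without compressed day 44 replicate 2, and 9 without normal day 316 replicate 1 or compressed day 156 replicate 2. It was 8 and 7 without compressed day 37 replicate 2 and day 51 replicate 2, and 6 and 5 without normal day 57 replicate 2 and day 260 replicate 2. Without normal days 57, 92, 260, 280 or 330 or compressed days 44, 180 or 198 it was 0, and without normal day 251 or 301 it was 11.

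At the same phase 0 hormone names were called, or 9 lower adjusted over the list alone, with a median of -0.33 in compressed pituitaries (18 arrays) against normal ones (17 arrays, camera adjusted p = 3.24e-08; adjusted p = 0.021 with an estimated correlation). The 5 called probes were B1160F02.4-like (-2.39 ± 0.32, 5.25-fold, adjusted p = 3.01e-05), phosducin-like protein 3 (1.25 ± 0.25), tyrosinase-related protein 1, an enzyme of pigment cells (-1.20 ± 0.20), plakoglobin, a junction protein (-1.02 ± 0.21), and leukocyte cell-derived chemotaxin 2 (0.54 ± 0.11). All but the first were named after their values were seen. Each of 38 of the 62 arrays moved the count by over 1.5 times, from 2 (normal day 316 replicate 1) to 77 (normal day 316 replicate 2) calls. Without the 3 arrays that resembled arrays of another tissue it was 3, and leaving out single days gave from 1 (compressed day 37 or 204, normal day 57) to 14 (compressed day 156).

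Over the gene lists, camera called 2 of 16 in liver, 1 of 19 in ovary and 1 of 15 in pituitary in at least 1 comparison. The others were not called in any of the 6 comparisons of their tissue, with a lowest adjusted p of 0.0954 in liver (lipid transport), 0.0704 in ovary (blood cells) and 0.0515 in pituitary (mitochondrial respiration). Median, mean and test differed in sign for 28 of 96 list results in liver, 30 of 114 in ovary and 24 of 90 in pituitary, and for 0 of the 10 called ones.

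Compressed days were then matched to the normal day they resembled most, to compare elapsed days with the phase of the shortened cycle. In the ovary 9 of 11 compressed days fell closer to the normal day of the same phase, and the mean error was 55.7 days for phase and 98.8 days for elapsed time, a difference of -43.1 days over 40 probes (exact permutation p = 0.0605, where the smallest possible is 0.000977). In the liver 9 of 12 days fell closer to phase, with mean errors of 90.9 and 109 days over 286 probes (exact permutation p = 0.407). In the pituitary only 3 probes changed across normal days, and the errors were 144 and 147 days (exact permutation p = 0.88). By this test, in none of the 3 tissues was phase shown to fit better than elapsed time. With Spearman in place of Pearson correlation the ovary difference was -46.3 days and passed (exact permutation p = 0.042), but without replicate 3 it was 12.9 days (exact permutation p = 0.582). The pituitary difference was -57.7 days without replicate 1 (exact permutation p = 0.00781).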

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

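The test of different day-0 pools for the liver acute phase genes and the dye-bias test of the pituitary hormone genes were the only tests here chosen after the results were seen.

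In the liver the late against early change differed between photoperiods, by the interaction test of limma, for 204 probes and for the acute phase, complement and clotting list (median 0.73, compressed minus normal). The named plasma proteins in that difference were serum amyloid P (4.19), serum albumin 2 (3.59), apolipoprotein A-I-1 (3.39), plasma retinol-binding protein II (3.04), coagulation factor XIII B (2.2), C-reactive protein (2.06), complement factor B (1.94) and apolipoprotein A-I-2 (1.93). Smaller differences were those of complement factor H (1.88), apolipoprotein CII (1.7), antithrombin-III (1.54), a putative 14 kDa apolipoprotein (1.52) and fibrinogen gamma (1.37). Outside the plasma proteins, VCRE3034 differed by 3.12 and protein disulfide-isomerase by 1.64, while glycerol-3-phosphate dehydrogenase 1-like protein differed by -2.81 and the vacuolar proton ATPase subunit a1 by -1.24. In the pituitary 3 probes differed between photoperiods, among them a rhotekin-2-like probe (2.99) and TMEM77 (2.15). Both stood above the pool on early normal days, as did Mx, so its open causes given below apply too.

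Of the 32 liver acute phase genes 14 rose against the day-0 pool on early normal days (median 0.51), where the list's call was lost with an estimated correlation (adjusted p = 0.169). By late days 14 fell, and that list call held (adjusted p = 0.00257). The normal array whose title and characteristics give different days was not the cause: without it and its compressed counterpart the list kept a camera adjusted p = 1e-15, in a range over 15 alternatives from 3.88e-16 to 0.00257. Nor was loess, since median centring gave an adjusted p = 1.07e-12. A different pool for each photoperiod would leave late against early days within the normal photoperiod at 0, and that median was -0.87. Background differed between the phases, with a median of 600.5 on early and 337.5 on late normal arrays, and 238.5 on early and 318.75 on late compressed ones. The 15 alternatives included no background subtraction and leaving out the 1 liver array of high background, but an effect of background was not tested further. Both photoperiods were measured on few early days (57 and 92 under the normal, 37 and 57 under the compressed one), so a state of the fish on those days, background or an unrecorded hybridisation batch stays open. A biological hypothesis is that some plasma protein transcripts may be higher in the early part of the normal cycle than later, and it was found and tested on the same arrays.

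The pituitary hormone list lay below the day-0 pool on the early compressed days (median -0.39), with 3 of 19 names called lower. The values argue against saturated spots as the whole cause: over the 10 of 19 names whose probe was saturated on no pituitary array the median was -0.37 (camera adjusted p = 4.4e-05 at the preset correlation). No estimated correlation was used for these 10 names. Several names of the list stand for the same hormone, so that p-value may be too small. A dye bias cancels between photoperiods at the same phase, where the list was still lower (camera adjusted p = 3.24e-08, in a range over 13 alternatives from 7.44e-09 to 0.021), which argues against it. Different day-0 pools for the photoperiods stay open for both values, because a pool richer in hormone transcripts could lower both.

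Splits of the arrays into other groups of the same sizes, 100 for each comparison with the real one included, gave a count as large 1 time for liver normal late against early (853 real, 96 highest other), 4 times for liver compressed (3 and 5), 1 time for the liver difference between photoperiods (204 and 30) and 1 time for liver at the same phase (581 and 1). These splits mix arrays of different days, so they ask only whether single arrays were assigned at random, and not whether any days differ. They were not adjusted over the comparisons. Random assignment is excluded at 0.05 for these liver comparisons, and likewise for ovary normal late against early (1 time, 188 and 5), ovary at the same phase (1 time, 57 and 13), pituitary normal late against early (4 times, 4 and 92), the pituitary difference (1 time, 3 and 1) and pituitary at the same phase (2 times, 5 and 21). Liver compressed and pituitary normal late against early, at 4 times each, were not set apart by the splits of whole days below. Random assignment is not excluded for ovary compressed late against early (13 times, 13 and 237), nor for the ovary difference (100 times, 0 and 1) or pituitary compressed late against early (100 times, 0 and 4). Splits that called several times the real count, in the compressed ovary, the normal pituitary and the pituitary at the same phase, point to a structure of the samples, and no test here shows what it is.

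Splits of whole days keep arrays of a day together. In ovary normal 1 of 35 called as many (188 real, 20 highest other), which excludes random grouping of days at 0.05, unadjusted. Background or batch differing between early and late days stays open. In liver normal the 15 splits are too few for a share under 0.05 (853 real, 252 highest other, with days 280 and 330 taken as early). Random grouping is not excluded for liver compressed, where 2 of 36 called as many (3 and 11, with days 180 and 198), for pituitary normal, 7 of 84 (4 and 24, with days 260, 280 and 316), or for pituitary compressed, 100 of 100 (0 and 1). In ovary compressed 14 of 36 called as many (13 and 475), the highest with days 198 and 216 taken as early, which include the weak arrays of day 198.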

How the results depend on the processing

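Leaving out each array, each day or the arrays that were weak, resembled another tissue or had high background or low signal was chosen only after the results were seen, unlike the other alternatives. Of 5548 values of named genes and lists under the alternatives, 4328 stayed on their side of the threshold, 1202 lost the call, 4 gained it and 14 reversed. Direction was compared only where either value was called, so uncalled values that changed sign count among the 4328. For each change given here the cause was not tested, except that leaving out arrays or days leaves fewer samples. Precision is limited by the number of arrays and by signal over background. Of the 28 arrays of low signal over background 12 were compressed ovary, 11 of these late. Of the 7 of high background 5 were late ovary.

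Without background subtraction the calls were 95 for liver compressed early against pool, 433 and 28 for ovary normal and compressed late against early, 108 and 38 for ovary normal and compressed early against pool, 105 for ovary at the same phase, 79 for pituitary compressed early against pool and 10 for the pituitary difference between photoperiods. Median centring gave 1463 for liver at the same phase, 554 and 52 for ovary late against early, 30 for ovary compressed early against pool, 159 for ovary at the same phase, 1 for pituitary compressed late against early, 66 and 68 for pituitary normal and compressed early against pool and 11 for pituitary at the same phase. Under it the median of all probes was -0.28 in place of -0.08 for ovary compressed late against early.

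Scaling between arrays gave, in liver, 448 and 7 (late against early), 1184 and 95 (early against pool) and 103 (difference). In ovary it gave 301 and 84, 325 and 157, 5 (difference) and 128 (same phase), and in pituitary 12 (normal late against early), 367 (normal early against pool), 22 (difference) and 20 (same phase). No filter on dim probes gave 400 for ovary normal late against early, 1 for the ovary difference, 65 for pituitary compressed early against pool and 3 for pituitary at the same phase. The authors' value table gave 98 for liver compressed early against pool. In ovary it gave 410 and 25 (late against early), 93 and 37 (early against pool) and 106 (same phase), and in pituitary 66 (compressed early against pool), 9 (difference) and 11 (same phase).

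With day as a random block the counts were 1 for liver compressed late against early, 130 for the liver difference, 257 for liver at the same phase, 80 and 2 for ovary late against early, 30 and 4 for ovary early against pool, 14 for ovary at the same phase and 0 for the pituitary difference. Array quality weights gave 8 and 113 for liver compressed late against early and early against pool. In ovary they gave 475 and 115, 567 and 309, and 21 for the difference, and in pituitary 12 (normal late against early), 615 and 78 (early against pool), 25 (difference) and 8 (same phase). Phases from 4 equal parts gave 459 for liver normal and 106 for ovary normal late against early. Without day 8 the ovary normal counts were 69 and 30. Without the weak arrays they were 23 for ovary compressed early against pool, 1 for pituitary compressed late against early, 247 and 105 for pituitary early against pool, 13 for the pituitary difference and 9 for pituitary at the same phase. Without the arrays that resemble another tissue they were 114 for ovary normal late against early, 25 for ovary at the same phase, 41 for pituitary normal early against pool, 0 for the pituitary difference and 3 for pituitary at the same phase.

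Without the arrays of high background the counts were 78 for ovary normal late against early, 1 for the ovary difference and 34 for ovary at the same phase. Without those of low signal over background they were 33 for ovary compressed early against pool, 12 and 37 for pituitary late against early, 193 and 157 for pituitary early against pool and 84 for the pituitary difference.

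Leaving out replicate numbers in turn gave, in liver, 440 to 624 and 0 to 4 (late against early), 1147 to 1517 and 12 to 26 (early against pool), 18 to 82 (difference) and 73 to 288 (same phase). In ovary the ranges were 55 to 142 and 0 to 11, 12 to 28 and 5 to 23, 0 to 1, and 0 to 320, and in pituitary 1 to 14 and 0 to 5, 9 to 67 and 18 to 38, 0 to 16, and 0 to 63. Of 10 called gene lists 5 were called with an estimated correlation. The alignment difference was -46.3 days in ovary with Spearman correlation and -57.7 days in pituitary without replicate 1, both then called, and it could not be computed without replicate 2 (liver, pituitary), 1 (ovary) or 3 (pituitary).

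Leaving out single arrays gave up to 1232 for liver normal late against early, 2277 for liver normal early against pool and 269 for the liver difference (each without normal day 92 replicate 2). It gave up to 62 for liver compressed early against pool (without normal day 220 replicate 1) and 716 for liver at the same phase (without normal day 330 replicate 1). In ovary it gave up to 671 for normal late against early (without day 260 replicate 3) and 358 at the same phase (without compressed day 198 replicate 2). In pituitary it gave up to 19 for normal late against early (without day 280 replicate 1), 402 for normal early against pool (without day 80 replicate 1), 85 for compressed early against pool and 77 at the same phase (without normal day 316 replicates 1 and 2 in turn).

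The titles' replicate numbers, which the descriptions contradict on 16 arrays, did not pair the samples. Samples of the same number had mean correlations of deviations from 0.0102 (liver compressed) down to -0.00472 (pituitary normal). Of the arrays, 14 of 35, 11 of 24, 6 of 31, 10 of 30, 8 of 33 and 8 of 29 matched their own number best. The replicate block gave 835 calls for liver normal late against early and moved no count by over 1.5 times. No batch of slides, printing or scanning is recorded, so none was run.

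Reversed values on early normal days against the pool in liver, without the arrays with disagreeing labels, were cytochrome c oxidase VIIa-related protein (0.08), phosphoenolpyruvate carboxykinase (0.01), succinate dehydrogenase b560 (0.02) and lysozyme g (0.02). Without the arrays of low signal over background these had the same values, and without replicate 1 the first and the third (0.06 and 0.05, against lowest values of -1.89 and -1.52 without another replicate). With the mean of all probes, aldolase B (-0.20 late against early, 0.13 against the pool) and liver fatty acid-binding protein (0.32) reversed in the normal liver, as did ribosomal protein S16 (0.18) in early normal pituitaries.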

Other observations

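Setting the interferon genes' medians against the spread of their members was chosen only after the result was seen, while the other tests in this part were not. Each hypothesis came from the same arrays.

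Several gene groups were not called as groups but had members mostly on 1 side of 0. In the normal ovary 62 of 73 ribosomal protein genes had late minus early values below 0, with a median of -0.30 against -0.16 for all probes (camera adjusted p = 0.193), as had 26 of 33 heat shock and stress genes (median -0.32, camera adjusted p = 0.376). At the same phase 26 of 33 heat shock and stress genes had compressed minus normal values above 0 in the ovary (median 0.25 against 0.07 for all probes, camera adjusted p = 0.225). Cell cycle genes had late minus early values below 0 under the compressed photoperiod in ovary (24 of 28, median -0.25 against -0.08, camera adjusted p = 0.282) and in pituitary (19 of 25, median -0.13 against -0.02, camera adjusted p = 0.18). Genes are not independent replicates, so these counts of genes carry no test of their own.

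The Mx probe stood above the day-0 pool on early normal days in all 3 tissues (2.54 ± 0.34 in liver, 1.95 ± 0.33 in ovary and 1.89 ± 0.33 in pituitary, SE) and not on early compressed days (-0.08 ± 0.34, -0.79 ± 0.52 and -0.87 ± 0.35). One hypothesis was an interferon response. Over 27, 27 and 26 other interferon genes the list was not called (camera adjusted p = 0.833 in liver, 0.833 in ovary and 0.833 in pituitary, medians 0.01, -0.02 and 0.01), with 0 members called in ovary and pituitary. The members had SDs of 0.54, 0.13 and 0.28, so the medians lay below the Mx values by more than that spread, and the highest members reached 1.54, 0.19 and 0.56. These values argue against a response of the whole list in each tissue. In liver the iip1 probe (1.54) and the VHSV-induced clones B32 (0.95) and B21 (0.82) rose. Interferon regulatory factor 7 (-0.68), interferon-induced protein 44 (-0.70) and another interferon inducible protein (-1.39) fell there, so only a response of few genes stays open in that tissue. A dye bias would be the same under both photoperiods, whereas the smallest of the 3 differences between them was 2.62 (± 0.49 SE). A different pool for the normal photoperiod would leave late against early days at 0, and the smallest of those 3 changes was -1.54 (± 0.41 SE in pituitary, adjusted p = 0.318, and ± 0.47 in ovary, adjusted p = 0.0765), beyond its SE but called only in liver. Against the pool, the call of Mx was lost without replicate 3 in ovary and in pituitary. A state of the fish on the early normal days, or an unrecorded batch of hybridisation shared by the early normal arrays of all tissues, stays open and could not be tested.

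The probe named ATP synthase subunit g that rose in the normal pituitary may measure a gonadotropin beta-2 transcript. If so, its deviations from day means should follow those of the 2 called gonadotropin beta-2 probes, and over 62 arrays the mean Pearson r was 0.84. Singly they were 0.79 (rho 0.8) and 0.88 (rho 0.84), each with a permutation p = 1e-05, the smallest that 100000 resamples can give, and 3.7e-05 after Benjamini-Hochberg adjustment over 11 relations. Without the 2 arrays farthest from the median, r was 0.75 and 0.84. With the 3 uncalled gonadotropin beta-2 probes r was lower, at 0.43, 0.40 and 0.71. The other 6 probes named ATP synthase subunit g gave a mean r of -0.12, from -0.45 to 0.24. The sequence of the probe was not used here, so its identity stays a hypothesis.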
